A study of Homo sapiens with 4 samples.

How the data were processed

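Gene expression in U2OS cells was measured on Affymetrix whole-transcript arrays, 1 array per sample, with total RNA labelled by the maker's WT PLUS chemistry, per the labels' protocols. 2 arrays were of cells given control siRNA and 2 of cells given BRPF3 siRNA, each at 50 nM for 48 hours. The groups and replicate numbers were taken from the sample titles. The value table deposited by the authors holds log2 values for 53617 probe sets. Per the submitters' processing notes these were made with RMA, a method that corrects background, normalizes between arrays and summarises the probes of a probe set. Its version, its settings and the probe set definitions are not given in the sources used here.

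The values ran from 0.80 to 13.57, with a median of 4.60 on each of the 4 arrays, so no further logarithm was taken and they were used as deposited. The arrays had near-equal but not identical distributions: the 25th percentile was 3.14 on both control arrays and 3.20 and 3.19 on the BRPF3 siRNA arrays. Normalization between arrays removes any shift common to all transcripts, so differences are relative to the bulk of the transcripts on an array. RMA values of dim probe sets lie close to background, which pulls their differences towards 0.

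Probe sets were named from a platform annotation, which gave exactly 1 gene symbol to 16098 probe sets and several to 0, and the other 37519 were unnamed here. All 16098 gene identifiers matched a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and also gave the class of each gene. The table was used for names alone. The named probe sets stood for 14884 genes, 779 of them with more than 1 probe set, for which the probe set with the highest mean over all arrays was used. Genes whose mean over the 4 arrays was under the median of all probe sets, 4.59, were left out, which left 10696 genes.

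The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without intensity trend, not robust, two-sided), with group as the model's factor. The fit had 2 residual degrees of freedom per gene and gained 3.81 from the prior. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. With 2 arrays against 2, an exact permutation test has 3 splits to compare and cannot come near that threshold, so the test rests on limma's sharing of variance between genes. A count of genes with a difference of at least 1.5-fold and separated arrays was made as a description without a p-value.

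Gene lists were tested with camera (preset correlation of 0.01 between genes), adjusted over the 23 lists with at least 3 tested members, of 27 fixed. The 22 gene lists cover chromatin acetylation, replication, the cell cycle, stress, metabolism, inflammation, bone, and the transfection route, and the 5 marker lists cover epithelial cells, leukocytes, endothelial cells, fibroblasts, and adipocytes with chondrocytes. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom of the fit. Few lists could pass there after adjustment, so a list that missed the threshold in that setting is not thereby shown to be unchanged. Fry tests whether the genes of a list move on balance 1 way and does not compare them with other genes. The median, mean and camera direction of a list differed in sign for the MYST complexes, origin licensing, osteoblast and leukocyte lists, and for none of these was a direction called. The members of 1 of the tested lists are not reported here.

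The test, the filter, the lists, most alternative settings and the rule for naming genes were fixed before the data were examined. The rule took BRPF3, the 12 largest rises and 12 largest falls among changed genes with separated arrays, the 2 highest and 2 lowest members of each list by moderated t, and 10 genes fixed by name. List members named beyond these 2 per direction (such as E2F2, ASF1B, KIF2C, ELP3, HDAC3, TRIB3, HMGCS1, LDHA, BNIP3, LAMP2, CTSB and CTSD) and PGAM4 were named after their values were seen. A test of BRPF3 itself was planned and could not be run, since no probe set is named for it here.

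The alternative settings fixed at that point were quantile normalization, centring each array on its median, the replicate number as a block, an intensity trend or robust fitting in eBayes, no intensity filter, a filter at the 75th percentile, the mean of all probe sets of a gene, an adjusted p under 0.1, a test without moderation, a fold of at least 2, and leaving out each array in turn. Cyclic loess normalization, protein-coding genes alone and the lysosomal list without GPNMB were added after the data were seen.

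The procedure was tested on simulated data with the variances of this fit, 10 sets of 10696 genes with 100 genes changed 1.5-fold and 100 changed 2-fold in each. It recovered 44.9% of the 1.5-fold and 91.2% of the 2-fold genes, 100% of them with the right sign, and 5.62% of its calls were unchanged genes. Since the variances came from this fit, these shares do not test whether the assumptions of the fit hold on these arrays. Each simulated set held 200 changed genes, while 1686 were called in the data. The adjustment depends on how many genes change, so the recovered shares do not carry over to the data. A list of 20 genes shifted by 0.25 was recovered at an unadjusted camera p under 0.05 in 10 of 10 sets. At an adjusted p under 0.05, 0 unshifted lists were called. The simulated genes varied independently, so this does not test camera on lists whose genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.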

Results

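Transcript levels were measured in U2OS cells, a human osteosarcoma line widely used in studies of the cell cycle and DNA replication. RNA was taken 48 hours after transfection with siRNA at 50 nM, either a non-targeting control siRNA or siRNA directed at BRPF3, a bromodomain protein that serves as scaffold of histone acetyltransferase complexes built on KAT7 (HBO1). Each group held 2 arrays, called biological replicates in the labels, and 10696 genes were bright enough to be tested. The number of arrays limits the precision. The labels do not say how separate the cultures of a group were, so p-values measure the spread between these arrays. Between the arrays of a group the log2 values of the tested genes differed with an SD of 0.17 for control siRNA and 0.20 for BRPF3 siRNA, while arrays of different groups differed with an SD of 0.31 to 0.32.

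The comparison asked which transcripts differ in abundance after depletion of BRPF3. BRPF3 itself was not analysed here, since the annotation used names no probe set of the table for it, so the knockdown stated in the labels was not checked on these arrays. For the same reason BRPF1, BRD1, KAT6A, ING4, ING5 and CDKN1A were not analysed here. The labels give no siRNA sequences, and no other siRNA against BRPF3 was analysed here, so effects of depletion and of the siRNA itself were not separated.

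After BRPF3 siRNA, KRT75, a keratin of the hair follicle, rose 3.05-fold (log2 difference 1.61 ± 0.08, limma's moderated SE, n = 2 arrays per group, as for all differences below). This SE draws the variance of a gene towards that of all genes, so it can be smaller or larger than the gene's own arrays give. HMOX1, the enzyme that degrades heme, rose by 1.58 ± 0.08 on the log2 scale. GPNMB, a glycoprotein of lysosomes and melanosomes, rose 2.65-fold (1.41 ± 0.08), FST, the activin antagonist follistatin, rose 2.58-fold (1.37 ± 0.09) and HOXB9, a homeobox gene, rose 2.42-fold (1.27 ± 0.09). The long noncoding RNA LINC02582 fell by 2.22 ± 0.17 on the log2 scale, and MAP2K6, a kinase that activates p38, fell by 2.13 ± 0.21. PGAM1, a glycolytic enzyme, fell by 1.40 ± 0.10, KIF3B, a motor subunit of kinesin-2, fell by 1.39 ± 0.09, and ACSL4, which activates long-chain polyunsaturated fatty acids, fell by 1.31 ± 0.08. PGAM1 has a near-identical copy, PGAM4, whose probe set fell by 1.16 ± 0.12, so the share of each gene in these differences is uncertain.

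The other genes among the 12 largest rises were GP6 (1.55 ± 0.19), the platelet collagen receptor, the tight junction protein CLDN1 (1.45 ± 0.15), the metalloprotease ADAM12 (1.45 ± 0.11), NIPAL4 (1.45 ± 0.10), PLXDC2 (1.35 ± 0.09), the caveolar ATPase EHD2 (1.30 ± 0.10) and CD22 (1.21 ± 0.16), a lectin of B cells. The other genes among the 12 largest falls were ARHGDIB (-1.39 ± 0.15), MYOCD (-1.35 ± 0.17), a coactivator of SRF, RASSF3 (-1.33 ± 0.09), the antisense RNA SH3PXD2A-AS1 (-1.31 ± 0.10), the mitochondrial peptidase MIPEP (-1.31 ± 0.11), ATF7IP2 (-1.30 ± 0.10) and RNF43 (-1.30 ± 0.15), a ubiquitin ligase acting on Wnt receptors. The BRPF3 siRNA means of LINC02582 (3.93) and ARHGDIB (4.28) lay under the intensity bound of 4.59, where differences are compressed, so the sizes of these falls are uncertain. Adjusted p-values of these 24 genes ran from 0.00756 to 0.0143 in limma's moderated test.

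**Figure D1:**
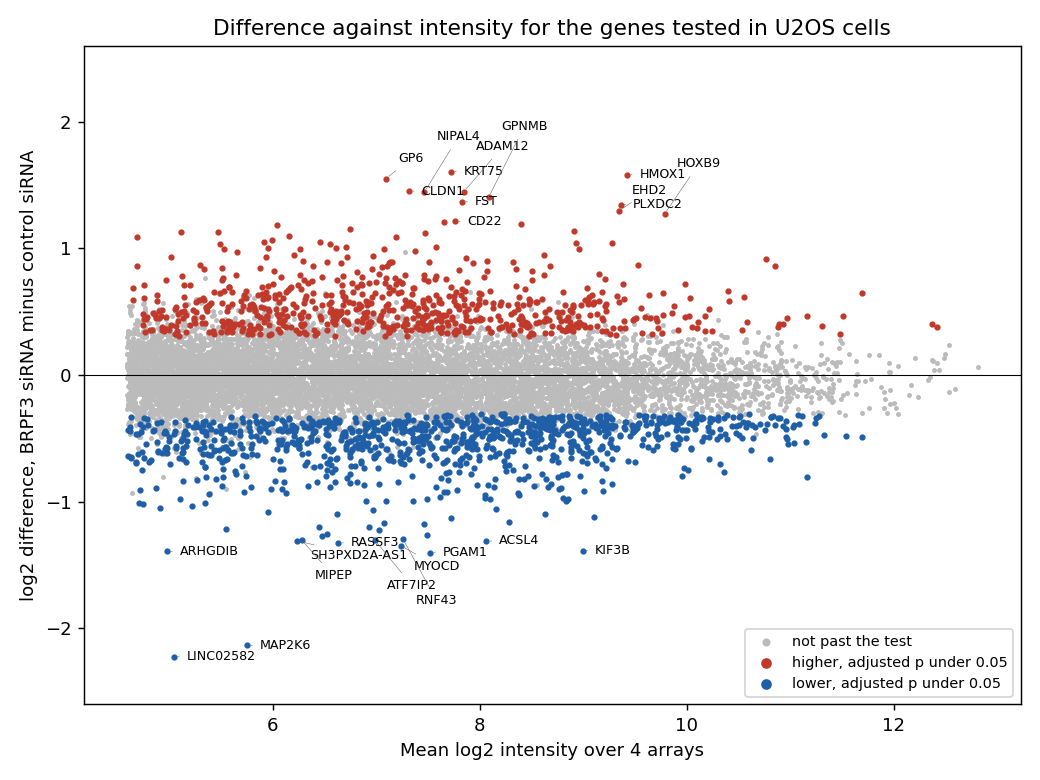
Each point is a gene, with its mean log2 intensity over the 4 arrays on the horizontal axis and the log2 difference between BRPF3 siRNA and control siRNA on the vertical axis. Red points (676 genes) rose and blue points (1010 genes) fell at an adjusted p under 0.05, grey points did not pass the test, and labels name the 12 largest changes in each direction.

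In all, 1686 of 10696 genes changed, of which 676 rose and 1010 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Each of the 1686 genes had separated arrays, with both BRPF3 siRNA arrays on the same side of both control arrays. A gene with overlapping arrays could not pass this test here, so their separation adds no support to the calls. Over all tested genes 63.2% had separated arrays, where 33.3% would be expected by chance. Most changes were small, with a median size of 1.40-fold, and 33 of the risen and 34 of the fallen genes changed at least 2-fold. A difference of at least 1.5-fold together with separated arrays was found for 544 genes, 235 higher and 309 lower, against 18 genes when the 4 arrays were split by replicate number and 5 when the numbers were crossed. These other splits place a control and a BRPF3 siRNA array in each group, so their counts are held low by the difference between the siRNAs itself and are no measure of chance. An unadjusted p under 0.05 was found for 3706 genes, where 534.8 would be expected by chance.

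The share of changed genes that fell was 59.9% on the deposited values and 48.4% after quantile normalization, where 764 genes rose and 718 fell, and 49.0% after cyclic loess normalization, where 766 rose and 736 fell. The number of changed genes was 0 without control replicate 1 and 0 without control replicate 2 (2446 and 2477 genes at an unadjusted p under 0.05), and 719 and 791 without BRPF3 siRNA replicate 1 and 2. The 24 genes with the largest changes all kept their direction under each of the 13 to 15 settings run for them. Their log2 differences were at least 1.04 in size throughout. Leaving out 1 array could not turn their direction, since they were chosen with separated arrays. Settings of block, trend, robust fitting, filter and moderation leave the difference as it is. The kept direction is therefore no further support for the calls.

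Among 23 gene and marker lists tested with camera, the list of endosomal and lysosomal genes was the 1 list that passed, with an adjusted p of 0.000604 at the preset correlation of 0.01 between genes. The list did not pass when the correlation was estimated (camera, adjusted p = 0.657 with an estimated correlation). In that setting 0 of the 23 lists passed and 0 had an unadjusted p under 0.05. The estimated correlation of the list, 0.025, was close to the preset value, and camera has 2 degrees of freedom there. The miss thus cannot be put down to correlation between genes alone. Of its 12 tested members 3 rose, 0 fell and 9 did not pass the test, and adjusted over the list alone 6 rose. GPNMB led the list, SQSTM1, the autophagy receptor p62, rose 1.47-fold (0.56 ± 0.08) and LAMP2, a membrane protein of lysosomes, rose 1.26-fold (0.33 ± 0.08). The differences of the proteases CTSB (0.31 ± 0.08, adjusted p = 0.0506) and CTSD (0.30 ± 0.08, adjusted p = 0.0600) did not pass the test over all genes. The difference was above 0 for 11 of the 12 members, with a median of 0.25, and the exception was MCOLN1 (-0.05 ± 0.08). Over the other camera settings the list's adjusted p ran from 8.58e-05 to 0.00609. Fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.0234. In all 5 lists passed fry, so passing it does not set this list apart.

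**Figure D2:**
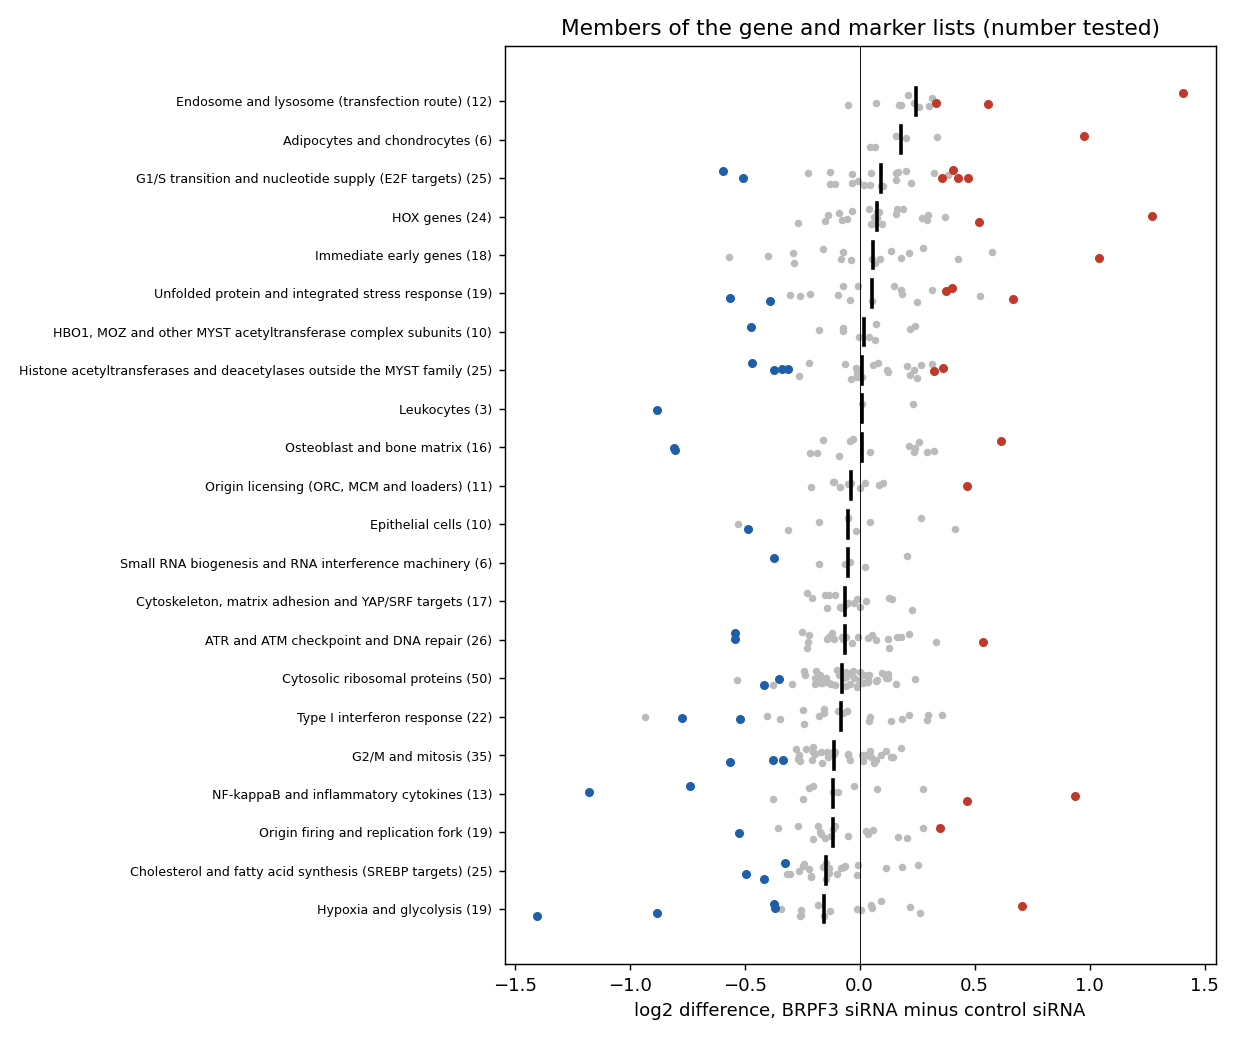
Log2 difference between BRPF3 siRNA and control siRNA (horizontal axis) of each tested member of the lists described in the text (vertical axis, number of tested members in parentheses). Red and blue points rose and fell at an adjusted p under 0.05 over all genes, grey points did not pass, black bars are list medians, and the endosome and lysosome list at the top has the highest median, 0.25.

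Adjusted camera p-values of the other lists ran from 0.136 to 0.816. Members of the lists described here are given as counts of the gene test over all 10696 genes and, beside them, of the test adjusted over the list alone.

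Among the genes that work with BRPF3, KAT7, the catalytic subunit of the HBO1 complex, differed by -0.00077 ± 0.08 (adjusted p = 0.995), its partner MEAF6 by -0.07 ± 0.09 (adjusted p = 0.628) and the related acetyltransferase KAT6B by -0.18 ± 0.08 (adjusted p = 0.175). Of 10 tested subunits of MYST-family acetyltransferase complexes, 0 rose, 1 fell and 9 did not pass, and adjusted over the list alone 0 rose and 1 fell. The fallen member was EPC2 (-0.47 ± 0.11), a subunit of the TIP60 complex. Among 25 acetyltransferases and deacetylases outside that family, 2 rose and 4 fell, the same numbers as adjusted over the list alone. HDAC9 (0.36 ± 0.08) and the coactivator NCOA1 (0.32 ± 0.08) rose, while HDAC4 (-0.47 ± 0.10), HDAC2 (-0.37 ± 0.08), ELP3 (-0.34 ± 0.08) and HDAC3 (-0.31 ± 0.08) fell. The BRPF3 siRNA mean of HDAC4 (4.44) lay under the intensity bound of 4.59, so the size of its fall is uncertain.

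Of 18 listed genes of origin licensing, 11 were named and tested: CDC6, CDT1 and MCM2 to MCM10. The ORC genes and GMNN were not analysed here. Of the 11, 1 rose and 0 fell (1 and 0 adjusted over the list alone): MCM8, a helicase related to the replicative MCM proteins, by 0.47 ± 0.09. MCM7 (0.10 ± 0.08, adjusted p = 0.422), MCM6 (-0.12 ± 0.08, adjusted p = 0.344) and the loader CDC6 (-0.21 ± 0.08, adjusted p = 0.135) did not pass. Among 19 genes of origin firing and the replication fork, 1 rose and 1 fell, also adjusted over the list alone. TIMELESS, a fork protection factor, rose 1.27-fold (0.35 ± 0.08), and PCNA, the sliding clamp of DNA polymerases, fell by 0.52 ± 0.08. CDC45, part of the replicative helicase, differed by 0.03 ± 0.08 (adjusted p = 0.849). Replication-dependent histone genes were not analysed here.

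Of 25 tested genes of the G1/S transition and nucleotide supply 4 rose and 2 fell (6 and 2 adjusted over the list alone). RRM2 (0.47 ± 0.09), a subunit of ribonucleotide reductase, E2F2 (0.43 ± 0.09), E2F8 (0.41 ± 0.08) and the histone chaperone ASF1B (0.36 ± 0.08) rose, whereas the cyclins CCNA2 (-0.59 ± 0.08) and CCNE1 (-0.51 ± 0.08) fell. Of 35 genes of G2/M and mitosis 0 rose and 3 fell (0 and 1 adjusted over the list alone), HMMR (-0.57 ± 0.09), CCNB1 (-0.38 ± 0.08) and the kinesin KIF2C (-0.33 ± 0.08). In the list of checkpoint and DNA repair genes 1 of 26 rose and 2 fell, also adjusted over the list alone. The checkpoint kinases CHEK1 (-0.54 ± 0.09) and CHEK2 (-0.54 ± 0.09) fell and the recombination factor RAD52 (0.54 ± 0.08) rose.

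**Figure D3:**
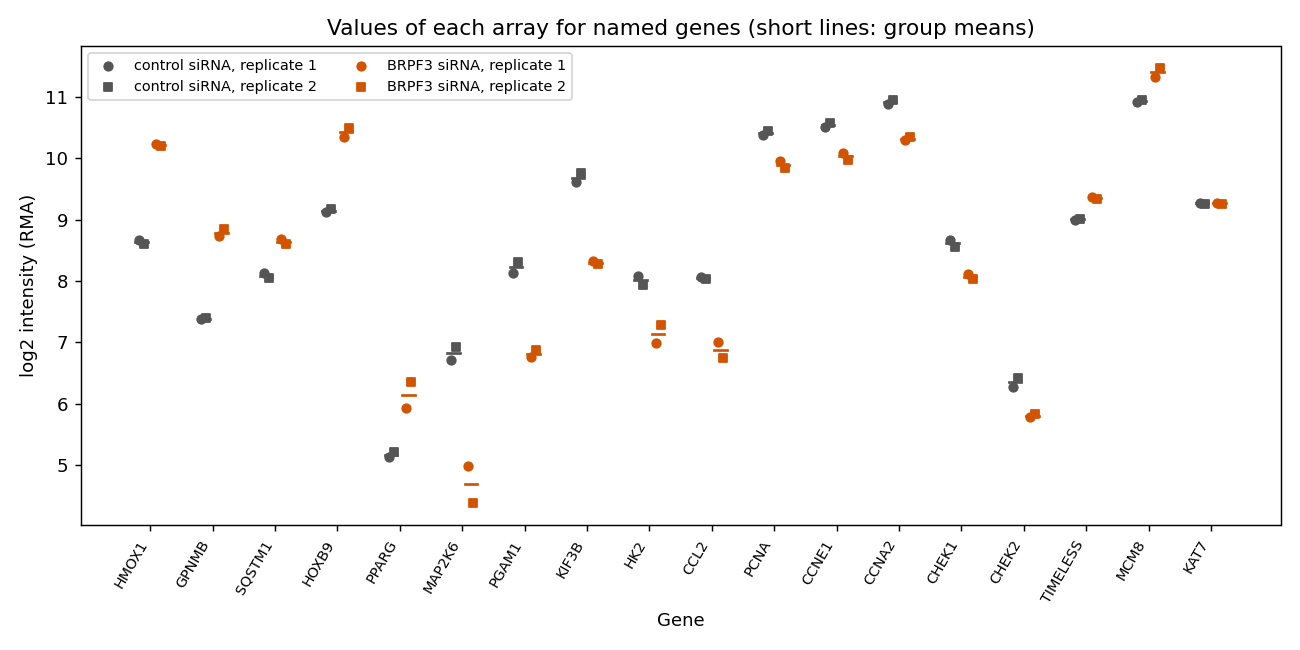
Log2 intensity (vertical axis) of 18 genes named in the text (horizontal axis) on each array, with control siRNA in grey, BRPF3 siRNA in orange, circles for replicate 1, squares for replicate 2 and short lines for group means. For KAT7 the 4 arrays overlap, while for HMOX1 both BRPF3 siRNA arrays lie above both control arrays by a mean of 1.58.

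Of 19 genes of the unfolded protein and integrated stress responses 3 rose and 2 fell (4 and 3 adjusted over the list alone). The lipoprotein receptor VLDLR (0.67 ± 0.12), the serine synthesis enzyme PSAT1 (0.40 ± 0.08) and the pseudokinase TRIB3 (0.38 ± 0.08) rose, and MANF (-0.57 ± 0.09) and the chaperone HYOU1 (-0.39 ± 0.08), both of the endoplasmic reticulum, fell. In the hypoxia and glycolysis list 1 of 19 rose and 4 fell, also adjusted over the list alone: LOX, a crosslinking enzyme of collagen (0.71 ± 0.10), rose, and beside PGAM1 the glycolytic enzymes HK2 (-0.88 ± 0.12) and LDHA (-0.37 ± 0.08) and the mitophagy receptor BNIP3 (-0.37 ± 0.08) fell. Of 25 genes of cholesterol and fatty acid synthesis 0 rose and 3 fell (0 and 1 adjusted over the list alone), the sterol enzymes MSMO1 (-0.50 ± 0.08), NSDHL (-0.42 ± 0.09) and HMGCS1 (-0.32 ± 0.08). Among 50 cytosolic ribosomal protein genes 0 rose and 2 fell (0 and 0 adjusted over the list alone), RPS26 (-0.41 ± 0.10) and RPL29 (-0.35 ± 0.09), which share sequence with processed pseudogenes and are uncertain for that reason. Mitochondrially encoded transcripts were not analysed here.

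CCL2, a monocyte chemokine, fell by 1.18 ± 0.11 and PTGS2, the inducible cyclooxygenase, fell by 0.74 ± 0.13, while TRAF1 (0.94 ± 0.13) and IRAK2 (0.47 ± 0.08) rose, so that 2 of 13 NF-kappaB and cytokine genes rose and 2 fell, also adjusted over the list alone. Of 22 genes of the type I interferon response 0 rose and 2 fell (0 and 4 adjusted over the list alone), the RNA sensor RIGI (-0.77 ± 0.10) and OASL (-0.52 ± 0.11). Among 18 immediate early genes 1 rose and 0 fell (4 and 1 adjusted over the list alone). That gene, the phosphatase DUSP1, rose by 1.04 ± 0.22 with an SD of 0.49 between the control arrays, and without control replicate 1 the list itself passed camera at the preset correlation (adjusted p = 0.00459, median 0.27). Its median was -0.18 without control replicate 2 and -0.11 without BRPF3 siRNA replicate 1, and on all 4 arrays the list had adjusted p = 0.839 with an estimated correlation. Of 6 genes of small RNA biogenesis 0 rose and 1 fell, also adjusted over the list alone, TNRC6B (-0.37 ± 0.08).

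Of 24 HOX genes and cofactors 2 rose and 0 fell (1 and 0 adjusted over the list alone), HOXB9 and HOXC8 (0.52 ± 0.12). Among 16 osteoblast and bone matrix genes 1 rose and 2 fell, also adjusted over the list alone: the growth factor BMP6 rose (0.61 ± 0.10), and its relative BMP4 (-0.81 ± 0.10) and the matrix proteoglycan LUM (-0.80 ± 0.08) fell. Of 17 genes of the cytoskeleton, matrix adhesion and YAP or SRF targets 0 rose and 0 fell in limma's test, also adjusted over the list alone, and 1 had an unadjusted p under 0.05. Among markers of other cell types, KRT18 (-0.49 ± 0.09) was the 1 of 10 epithelial markers that fell, with 0 risen (2 and 2 adjusted over the list alone). LAPTM5 (-0.88 ± 0.13) fell among 3 leukocyte markers with 0 risen, also adjusted over the list alone. PPARG (0.98 ± 0.14), the adipogenic nuclear receptor, rose among 6 adipocyte and chondrocyte markers with 0 fallen, also adjusted over the list alone. Of the 2 tested fibroblast markers LUM fell and THY1 (0.21 ± 0.08) did not pass over all genes (1 risen and 1 fallen adjusted over the list alone), and the endothelial markers CLDN5 (-0.10 ± 0.08) and ERG (-0.03 ± 0.10) did not pass by either count.

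Of the 69 changed genes singled out by the naming rule, quantile normalization ended 6 calls (EPC2, CCNB1, HYOU1, NSDHL, RPS26 and RPL29) and cyclic loess 7 (the same genes and TNRC6B). Testing all genes without an intensity filter ended 33, among them PCNA, CCNE1, CHEK1 and CHEK2, leaving out either control array ended all 69, and leaving out BRPF3 siRNA replicate 1 or 2 ended 22 and 28. TIMELESS, RRM2, E2F8, CCNB1, HDAC2, HDAC4, HDAC9, NCOA1, HOXC8, MANF, HYOU1, PSAT1, NSDHL, RPS26, RPL29, DUSP1 and TNRC6B lost their calls whichever of the 4 arrays was left out.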

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

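The test of probe sets without a gene name was chosen after the results for named genes were seen. Among 15344 probe sets that passed the intensity filter but carry no gene name here, and so enter no comparison of the report, 3896 had an unadjusted p under 0.05, 1694 higher and 2202 lower after BRPF3 siRNA, where 767.2 would be expected by chance. None passed limma's adjusted test, with a smallest adjusted p of 0.0668, while 1349 passed with an intensity trend in eBayes, 479 risen and 870 fallen. These probe sets had a fit and an adjustment of their own. That fit gained 2.36 degrees of freedom from its prior, against 3.81 for the named genes. The lack of calls therefore cannot be set against the calls among named genes. They drew attention as a signal in data that the report leaves aside, and no explanation was tested.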

How the results depend on the processing

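Cyclic loess normalization, protein-coding genes alone and the list without GPNMB were tests chosen after the data were seen. The number of changed genes, 1686, moved to 2645 with an intensity trend, 409 without an intensity filter (with more and dimmer genes tested), 2877 at an adjusted p under 0.1 and 1 without moderation, and ran from 0 to 791 with an array left out. It was 0 without either control array, and there a group's lone array is assumed to vary like the other group. Between 1482 and 2183 genes changed under the remaining alternatives. The count of genes at least 1.5-fold apart with separated arrays, 544, was 67 at a fold of at least 2, since that bound is larger, and 520 to 685 under other settings. With an array left out, 1 array is set against 2 and separation is easier to meet, so that count cannot be compared with 544. The 1 list past camera became 0 with an estimated correlation, where camera has 2 degrees of freedom, and 5 with fry, which asks another question. Camera gave 1 to 2 lists with an array left out and 1 list otherwise, and without GPNMB the lysosomal list kept an adjusted p of 0.00609 at the preset correlation, and had adjusted p = 0.189 with an estimated correlation, over 10 lists tested apart. With the replicate number as a block 1604 genes changed and 1 list passed. The same-numbered arrays share only a number, their deviations correlated at 0.14 across genes over 2 pairs, and a call lost under the block is not read as a weaker effect. None of the 69 changed genes of the naming rule changed sign under the alternatives run for it. With an array left out none could, since the arrays of every changed gene were separated. The cause was not tested where the construction of an alternative does not give it. The alternatives planned for BRPF3 itself were not run, as no probe set is named for it here. Near background, differences of dim genes are compressed, and genes under the filter entered the setting without it.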

Other observations

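The gene families and the class of long noncoding RNAs described here, and the tests on them, were chosen after the called genes had been seen, as were the tests on mitochondrial ribosomal proteins, while the NRF2 and lysosomal lists were written down before their own values were looked at. Camera p-values given here were adjusted over the 10 families and lists tested in this part. With an estimated correlation 0 of the 10 passed, with 2 at an unadjusted camera p under 0.05 (mitochondrial ribosomal proteins, 0.0154, and nucleolar factors, 0.0340). That setting has 2 degrees of freedom, so a miss there does not decide whether a family changed.

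Among genes for the mitochondrial ribosome, 16 of 73 tested fell and 0 rose, with a median log2 difference of -0.25. MRPL1 (-0.85 ± 0.08, limma's moderated SE, n = 2 arrays per group) and MRPL44 (-0.66 ± 0.09) led the falls. Of 47 nucleolar factors of ribosome assembly 25 fell and 0 rose, with a median of -0.35, among them NOC3L (-0.89 ± 0.08), NSA2 (-0.80 ± 0.08) and RPF1 (-0.62 ± 0.08). Of 22 subunits of the mitochondrial import machinery 8 fell and 0 rose, with a median of -0.17, led by TOMM20 (-0.66 ± 0.08). Of 24 nuclear genes of the respiratory chain and ATP synthase, most of them for cytochrome c oxidase or complex III, with no subunits of complex I or of the core of ATP synthase, 1 fell, COX6C (-0.43 ± 0.10), and 0 rose, with a median of -0.10, at the 15.8 percentile of 10000 random lists of matched intensity. Camera gave adjusted p-values of 6.52e-09, 6.52e-09, 0.00414 and 0.0664 for these families in that order, and 0.154, 0.170, 0.217 and 0.226 with an estimated correlation. The median of the import genes lay at percentile 2.96 of its random lists, within their central 95%. After cyclic loess 11, 13, 4 and 1 genes of the families fell, and the medians were -0.20, -0.27, -0.09 and -0.08.

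Of 24 genes of intraflagellar transport, which builds cilia, 12 fell and 0 rose, with a median of -0.42 (camera, adjusted p = 0.000268, and adjusted p = 0.189 with an estimated correlation). Beside KIF3B these included WDR35 (-0.87 ± 0.08), DYNC2I1 (-0.83 ± 0.12), CLUAP1 (-0.69 ± 0.12), IFT81 (-0.59 ± 0.10) and KIF3A (-0.43 ± 0.08), and 12 fell after cyclic loess too. The family was chosen after KIF3B had been seen among the largest falls, and it was not tested without that gene. In the protocadherin beta cluster, a tandem array of related cell adhesion genes, 6 of 12 tested genes fell and 0 rose, with a median of -0.51 (camera, adjusted p = 0.000544, and adjusted p = 0.189 with an estimated correlation), among them PCDHB12 (-0.88 ± 0.17) and PCDHB15 (-0.69 ± 0.10). These paralogs share sequence, so their probe sets may not be independent, and the median was -0.50 after cyclic loess. Beside KRT75, the keratins KRT33B (0.93 ± 0.12) and KRT20 (0.86 ± 0.09) rose and KRT18 fell among 17 tested, and the family as a whole did not pass (limma's camera, adjusted p = 0.214).

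The lower values of the mitochondrial ribosomal protein genes were weighed against properties of the arrays. Their median of -0.25 lay at percentile 0 of 10000 random lists of matched intensity, whose own median was -0.05. The lower values thus went beyond those of single genes of like intensity. The random lists draw genes independently, while genes of a family can move together, so the percentile is no test of the family. After cyclic loess the median was -0.20, so that scaling did not remove the lower values. The unadjusted camera p there was 1.80e-08 at the preset correlation. With an estimated correlation, run on the deposited values alone, the family did not pass (camera, adjusted p = 0.154). The family and both checks were chosen after the called genes had been seen, so neither check excludes a cause. Whether BRPF3 siRNA lowers the output of mitochondrial ribosome genes stays open, since no test on data apart from those that prompted the question was run. An effect specific to this siRNA but not due to BRPF3 stays open too, since the labels give no siRNA sequences and no other siRNA against BRPF3 was analysed here.

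More changed genes fell than rose on the deposited values, 59.9%, but 48.4% after quantile and 49.0% after cyclic loess normalization, so the surplus of falls may come from the scaling of the arrays, though centring each array on its median left it at 56.4%. The median difference of probe sets ran from 0.13 in the dimmest of 10 equal classes of intensity to -0.08 in the brightest. A lone BRPF3 siRNA array did not account for the surplus, since the share was at least 57.6% with either left out. Among long noncoding RNAs the balance was the other way, 49 risen and 17 fallen, against 581 and 948 protein-coding genes (Fisher's exact p = 7.87e-09), and after cyclic loess 52 and 15 against 669 and 689 (Fisher's exact p = 4.34e-06). After cyclic loess and within 10 classes of intensity the long noncoding RNAs stayed higher by 0.08 on average. The stratified permutation p was 0.0001, the smallest that 10000 permutations can give. Matching for intensity thus did not remove the difference on these arrays. The Fisher and permutation tests count genes as independent, while all genes were read on the same arrays and can move together. Their p-values measure the spread between genes and not between cultures, so they are no test of the class.

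The higher values of the lysosomal list did not rest on GPNMB alone, without which limma's camera gave adjusted p = 0.000544 (0.000265 unadjusted) at the preset correlation. The list's median of 0.25 lay at percentile 99.98 of random lists of matched intensity, so it went beyond that of single genes of like intensity. Those lists draw genes independently, and this list was followed up because it had passed camera, so the percentile is no test of the list. Of 54 lysosomal genes set down outside the list, 24 were named here and 21 tested. These went both ways: of 21 tested, ARSA, PSAP, GRN and TPP1 rose and CTSO, TMEM192 and CTSC fell (limma's camera, adjusted p = 0.262, 0.235 unadjusted). It had been set down beforehand that such a p would exclude a change across lysosomal genes in general, but with members on both sides it excludes nothing, so whether such a change exists stays open. With an estimated correlation the list did not pass, nor did it without GPNMB (adjusted p = 0.189). Control cells were transfected too, and an effect specific to the BRPF3 siRNA but not due to BRPF3 was not tested.

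A hypothesis that the rise of HMOX1 is part of a rise across NRF2 targets was tested on 13 other targets. These were the ones named here of 32 listed, so most of the list was not measured. Of the 13, BLVRB and TXNRD1 rose and UGDH fell, with a median of -0.21 (limma's camera, adjusted p = 0.487 and the same unadjusted). Both bounds set down beforehand as excluding it, a p of at least 0.05 or a downward direction, were met, with 4 of the 13 higher. They were too loose: the direction was not beyond the spread of the members, whose mean was -0.05, and a p that misses the threshold excludes nothing, so the question stays open.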
